A study of Punica granatum with 4 samples.

How the data were processed

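Transcript abundance was measured by RNA sequencing in leaves of pomegranate (Punica granatum, the strain labelled Hongmanao). Per the labels' protocols, rooted cuttings were grown for 90 days, soil water was then held at 30% to 35% of field capacity, and plants were sprayed daily with 5 mL of water or of abscisic acid (ABA) at 30, 60 or 90 µM. The age given for the plants was 180 days in all 4 libraries. Total RNA was extracted with TRIzol and the libraries were made with a NEBNext Ultra RNA kit, per the labels' protocols. Whether RNA was selected by its poly(A) tail or depleted of rRNA is not given in the sources used here. There were 4 libraries, 1 per dose, and the labels do not say whether a library came from 1 plant or from several.

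The deposited values are raw read counts per gene, whole numbers that the authors had not normalized. FastQC, HISAT2 (an aligner) and featureCounts (a read counter) are named in the submitters' processing notes. Their versions, the genome build, the strand setting and the treatment of reads that map to more than 1 place are not given in the sources used here. Reads shared between near-identical or overlapping genes could therefore have been counted, split or dropped, and antisense genes cannot be told apart from their partners. The table held 27893 features, and 0 of its columns belonged to other samples.

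Of these identifiers, 27509 matched a gene symbol and 37 a locus tag in the RefSeq gene table of the assembly ASM765513v2, and 347 were not matched. That table was used for names, for the class of a feature (protein-coding, lncRNA, rRNA, snoRNA or snRNA) and for which genes neighbour each other. Because no build is named for the counts, no coordinates are given. For nearly every gene the symbol in that table is its LOC identifier, and neither the table nor the counts pair it with a product description. The 52 gene lists fixed before the data were examined (ABA signalling, drought protection, photosynthesis, hormones, tannin synthesis, markers of other tissues and others) were defined by product descriptions or organelle gene symbols. None of the 52 lists could be filled, with 0 members found, so no statement is made about any of them. Feature classes took their place, a choice made after the data were examined.

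Features with at least 1 CPM (a count scaled to library size) in at least 1 library were kept, 19286 in all. Libraries were scaled with edgeR's TMM factors, which lay between 0.940 and 1.03. A gene was called higher or lower between 2 libraries when the exact 95% conditional binomial (Clopper-Pearson) interval of the ratio of its scaled counts lay wholly above 2 or wholly below 0.5. This is a rule of size and not a test, because with 1 library per dose there is no measure of the spread within a dose. The intervals, and the floor of 3 counts used where a library had none, cover counting error only. The floor applies to the library with 0 counts, leaves out the counting error of the other library, and is rounded down to a whole fold. The exact interval starts lower, for example at 92.7 against 114 for LOC116207036 at 30 µM. Reads amplified by PCR without molecular identifiers are not independent molecules. Log2 folds used a prior count of 2. Class medians were set against 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Shares of library counts carry exact (Clopper-Pearson) 95% binomial intervals.

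Tests with a spread between libraries were possible in 2 fits of edgeR's quasi-likelihood test, each with 2 residual degrees of freedom and Benjamini-Hochberg adjustment. The first fitted a straight line in dose, so that its spread is the departure of the 4 libraries from that line. The second set the 3 ABA libraries against the control library, with the doses standing in as replicates and the lone control library assumed to vary like the others. Both were tested on simulated data with 200 of the 19286 genes changed 4-fold. The changed genes were drawn from those with a mean of at least 100 counts, so recovery among genes with fewer counts was not simulated. With a biological coefficient of variation of 0.1 the dose line recovered 100.0% of the changed genes and the control comparison 100.0%. With the spread estimated over these 4 libraries the recovered shares were 0% and 2.0%. For the same changed genes, the size rule recovered 100.0% of 4-fold changes between 2 simulated libraries that otherwise differed by counting error, with 0 wrong calls. Unchanged genes that vary by counting error alone rarely pass a 2-fold bound, so that 0 is no error rate for real libraries. The common biological coefficient of variation over the 3 ABA libraries, dose differences included, was 0.337.

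Library sizes ran from 22118468 to 28366719 counts, and 3 counts corresponded to 0.104 to 0.131 CPM. Genes to be named were set by rules fixed at the same time as the lists. They were the 5 largest and 5 smallest folds per dose and the 3 per direction between neighbouring doses. They also took in the 10 per direction that met the size rule at all 3 doses, the 5 most significant per direction among genes past the adjusted threshold in each fit (there were none), and the 5 most abundant genes. A mean CPM of at least 5 was required, except of the most abundant genes. Because the identifiers carry no function, only the first 2 per direction of each rule are printed. The rRNA, snoRNA, on/off and neighbouring genes named outside these rules were chosen after their values were seen. A condition on product descriptions was dropped, as the rule had provided for. Comparisons of doses with the shared control were set against 20 simulations of unchanged libraries whose spread was that of the 3 ABA libraries, dose differences included. Alternatives covered the scaling, the filter, the size rule, the tool and the libraries used. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.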

Results

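Leaf transcriptomes of pomegranate plants held under drought were compared across 4 doses of the hormone ABA, which plants make in drying tissue and which closes stomata. The control plants were sprayed with water (0 µM) and the others with 30, 60 or 90 µM ABA. Each dose was represented by 1 library, so no difference below has a replicate check. The libraries held 22118468 counts at 0 µM, 24052618 at 30 µM, 28366719 at 60 µM and 26590290 at 90 µM. Between 22044 and 22257 features had at least 1 count. The 10 most abundant features took 3.01% of the counts at 0 µM and 3.57% at 90 µM. Protein-coding genes took 99.1% of the control library, lncRNA features 0.531% and rRNA features 0.334%.

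The first question was which genes differed between each dose and the control. At 30 µM, 316 genes were more than 2-fold higher and 385 more than 2-fold lower than in the control library, 3.63% of the 19286 genes kept. Protein-coding genes made up 297 of the higher and 342 of the lower ones, and lncRNA genes 19 and 43. LOC116190225 had 2 counts in the control and 1539 at 30 µM, a ratio of 722 with a counting interval from 200 to 5970 (0.0875 against 63.2 CPM). LOC116207036 had 0 control counts and 366 at 30 µM, at least 114-fold higher. LOC116210933 went the other way, from 1452 counts to 0, at least 515-fold lower, but had 1740 counts at 60 µM. LOC116189976 had 673 control counts, 0 at 30 µM and 1133 at 60 µM. When genes had to reach 1 CPM in all 4 libraries, the counts were 188 higher and 198 lower.

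At 60 µM, 688 genes were more than 2-fold higher and 569 more than 2-fold lower than in the control library. Of these, 665 and 550 were protein-coding, and 23 and 19 were lncRNA genes. LOC116190225 had 2 control counts and 2184 at 60 µM, a ratio of 866 (interval 239 to 7154). LOC116207036 reached 465 counts, at least 122-fold above the control. LOC116190357 was 159-fold lower (interval 118 to 221), with 5307 control counts and 42 at 60 µM, while it had 8383 counts at 30 µM. LOC116190360 had 156 control counts and 2 at 60 µM, 98.4-fold lower (interval 26.8 to 820).

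At 90 µM, 731 genes were more than 2-fold higher and 790 more than 2-fold lower than in the control library, 7.89% of those kept. Protein-coding genes made up 702 of the higher and 729 of the lower ones, and lncRNA genes 29 and 56. LOC116208707 had 1 control count and 1809 counts at 90 µM, a ratio of 1655 with an interval from 297 to 65406. Its counts at the doses between were 281 and 531. LOC116190225 was 902-fold higher (interval 249 to 7454). LOC116210933 had 0 counts, at least 529-fold lower than in the control. LOC116209956 had 3 counts at 90 µM against 2050 in the control, 747-fold lower (interval 255 to 3625), and 3683 at 60 µM. Scaled by total counts instead, which moves the median log2 fold of all genes at 90 µM by -0.14, the split was 603 higher and 1025 lower. With 1 CPM required in all 4 libraries it was 544 higher and 498 lower, and with a 4-fold threshold 198 and 171, so which direction held more genes depends on the setting.

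**Figure D1:**
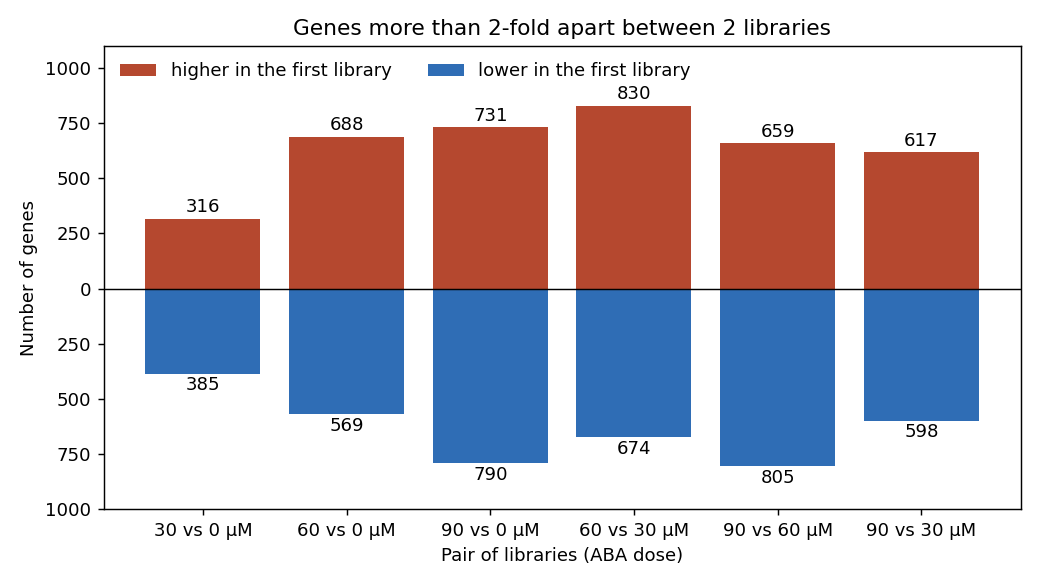
Number of genes more than 2-fold higher (upward bars) or lower (downward bars) in the first library of each pair, by the exact 95% counting interval, with 1 library per dose. The pair 30 against 0 µM has the fewest genes (316 and 385), and the pair 90 against 0 µM the most (731 and 790). The pair 60 against 30 µM comes close (830 and 674), and passes it with 1 CPM required in all 4 libraries (568 and 517 against 544 and 498).

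Of the 2530 genes that differed from the control at any dose, 71 were higher at all 3 doses and 69 lower at all 3. Among the higher ones, LOC116190225 had 63.2 to 79.0 CPM in the ABA libraries and LOC116207036 had 15.0 to 21.3 CPM, against 0.0875 CPM and 0 counts in the control. Among the lower ones, LOC116191974 had 592 control counts and 9, 17 and 9 at 30, 60 and 90 µM, and LOC116190386 had 2083 control counts and 114, 73 and 94. Of the 5 most abundant genes, LOC116208007 was higher than the control at each dose, 3.82-fold (interval 3.77 to 3.87), 3.78-fold and 2.38-fold. LOC116198126 was 1.77-fold, 2.65-fold and 2.18-fold higher. LOC116209490 was 1.19-fold, 1.44-fold and 1.84-fold higher. LOC116204098 was 0.661, 0.488 and 1.07 times its control level (a log2 fold of 0.10 at 90 µM that was -0.04 when scaled by total counts), and LOC116215619 was 1.05, 0.677 and 1.11 times its own.

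The same control library entered each of these comparisons. In simulated unchanged libraries with the spread of the 3 ABA libraries, on average 106 genes came out higher (124 at most) at all 3 doses. Those lower at all 3 doses averaged 67.3 (82 at most). Neither observed number lay above the simulated range. The spread used includes any differences between the doses, so a number not above that range does not show that these genes are unchanged. The simulated libraries gave 1242 to 1265 calls per dose on average, against 701, 1257 and 1521 observed. Genes higher at both 60 and 90 µM numbered 322, against 204 on average (219 at most) in the simulations and 26.1 for independent lists. Genes lower at both 30 and 90 µM numbered 221, against 155 (172 at most) and 15.8. The remaining same-direction pairs of doses lay within or below the simulated values: 102 genes higher at both 30 and 60 µM (204 simulated), 106 lower at both (156), 159 higher at both 30 and 90 µM (206) and 150 lower at both 60 and 90 µM (154). The control has 1 library and could not be split, so part of any overlap may come from sharing it.

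The second question was how the doses differed from each other. Between 30 and 60 µM, 830 genes were more than 2-fold higher and 674 more than 2-fold lower at the larger dose. LOC116210933 went from 0 to 1740 counts (at least 489-fold) and LOC116189976 from 0 to 1133 (at least 318-fold). LOC116190357 was 236-fold lower at 60 than at 30 µM (interval 175 to 328) and LOC116213047 had 582 counts at 30 and 1 at 60 µM. Between 60 and 90 µM, 659 genes were more than 2-fold higher and 805 lower at the larger dose (501 and 961 when scaled by total counts, 497 and 515 with 1 CPM required in all 4 libraries). LOC116213047 went from 1 to 633 counts and LOC116210303 from 0 to 332 (at least 127-fold). LOC116210933 went from 1740 to 0 counts, and LOC116209956 from 3683 to 3. Libraries at 30 and 90 µM differed by 617 and 598 genes. Across genes, which are not independent replicates, the rank correlation was highest for 0 with 30 µM (Spearman's rho 0.972) and lowest for 30 with 60 µM (0.954). Pearson's r on log2 values ordered the pairs differently, with the highest for 30 with 90 µM (0.952, against 0.951 for 0 with 30 µM) and the lowest for 0 with 90 µM (0.929).

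No gene passed either of the 2 edgeR tests that use a spread between libraries. For a straight line in dose, 0 of 19286 genes had an adjusted p under 0.05 in edgeR's quasi-likelihood test, the smallest being 0.485. At an unadjusted p under 0.05 there were 746 genes with a rising and 616 with a falling line, 1362 in all, where 964 would be expected by chance. For the 3 ABA libraries against the control, 0 genes passed the same edgeR test, the smallest adjusted p being 0.144, and 302 genes were higher and 262 lower at an unadjusted p under 0.05 (564 in all, fewer than the 964 expected by chance, and 931 without the 30 µM library). DESeq2 on the same designs called 237 rising and 70 falling genes, and 53 higher and 24 lower ones, while limma-voom called 0 in both. At an unadjusted p under 0.05, DESeq2 had 1616 and 798 genes and limma-voom 1320 and 561. At the spread of these libraries, dose differences included, neither edgeR fit recovered more than 2.0% of simulated 4-fold changes. These zeros therefore do not exclude changes of that size, and other sizes were not simulated.

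Of the non-coding classes, rRNA had a median outside the range of 95% of matched random lists at each dose, lncRNA at 30 µM, and snoRNA and snRNA at none. At 90 µM, 10 of the 11 rRNA features kept had a lower scaled count than in the control, with a median log2 fold of -0.98. None of 10000 random lists matched on expression had a median as low (95% of them lay between -0.36 and 0.39). The rRNA medians were -0.56 at 30 µM (percentile 0.10) and -0.42 at 60 µM (percentile 1.81). LOC116190117, an abundant rRNA feature, had 21254 counts at 0 µM, 14278 at 30 µM, 19741 at 60 µM and 10354 at 90 µM, and LOC116190074 had 23123, 19355, 21796 and 13102. rRNA genes are near-identical copies that can share reads, so the values of single features are uncertain. The random lists hold genes drawn singly, so the percentiles do not allow for features that move together and can overstate how rare these medians are. The class took 0.334% of counts at 0 µM (interval 0.332% to 0.337%), 0.228% at 30 µM, 0.243% at 60 µM and 0.146% at 90 µM (0.144% to 0.147%).

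Of the 13 snoRNA genes kept, which guide the modification of rRNA, 11 were below their control level at 90 µM, with a median log2 fold of -0.84 at percentile 3.0 of matched random lists, inside the range that held 95% of them (-0.87 to 0.37). Their medians at 30 and 60 µM were -0.20 and -0.08, at percentiles 32.1 and 40.4. With 1 CPM required in all 4 libraries the snoRNA median at 90 µM was -1.06, which was not set against random lists made with that filter. LOC116198344 had 348 snoRNA counts in the control and 322, 254 and 157 at the rising doses. The snoRNA class took 0.00681% of counts at 0 µM (interval 0.00647% to 0.00716%) and 0.00388% at 90 µM (0.00365% to 0.00413%). The 3 snRNA genes kept had medians of 0.07, -1.07 and -0.43 and percentiles of 63.2, 3.15 and 36.0. With 1 CPM required in all 4 libraries the snRNA medians at 60 and 90 µM were -0.03 and 0.58, so their direction at 90 µM depends on the filter. That filter drops LOC116189699, which had 16 counts at 60 µM. The 684 lncRNA genes had a median of -0.14 at 30 µM (percentile 0.12), -0.03 at 60 µM (percentile 28.1) and -0.19 at 90 µM (percentile 12.6). At 30 µM, 95% of the random lists lay between -0.11 and -0.01. With 1 CPM required in all 4 libraries the lncRNA median at 30 µM was -0.0799 over 437 genes, at percentile 1.37 of random lists made with that filter (95% of them between -0.07 and 0.03). The median was -0.32 at 90 µM when scaled by total counts. More than 2-fold lower lncRNA genes were 6.29% of the class at 30 µM and 8.19% at 90 µM, against 1.84% and 3.92% of protein-coding genes, but 2.78% against 2.96% at 60 µM. The shares more than 2-fold higher were 2.78%, 3.36% and 4.24% of lncRNA genes and 1.60%, 3.58% and 3.78% of protein-coding genes at 30, 60 and 90 µM. These shares were not matched on expression. At 90 µM, 95% of the matched random lists had medians between -0.21 and -0.09, a range that holds the lncRNA median, so the larger share there is not shown to be particular to lncRNA genes.

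**Figure D2:**
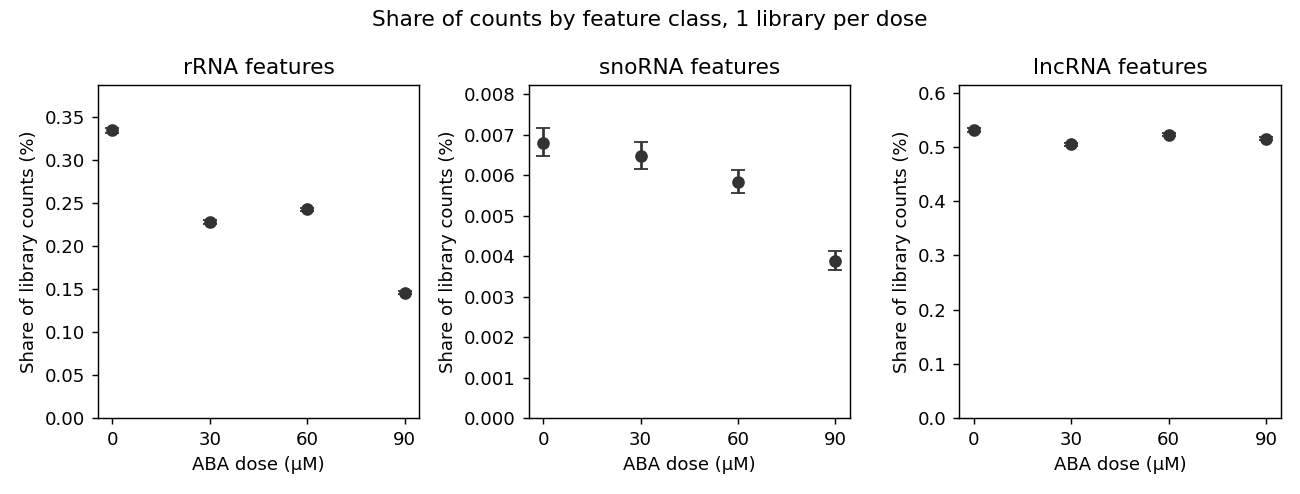
Share of each library's counts (percent, vertical axes from 0) held by rRNA, snoRNA and lncRNA features at each ABA dose (µM); points are single libraries and bars are exact 95% binomial intervals, which cover counting error only. The rRNA share is lowest at 90 µM (0.146%) and highest at 0 µM (0.334%), while the lncRNA share stays between 0.505% and 0.531%.

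A set of genes had many reads in some libraries and almost none in others. With on set at 100 counts or more and off at 10 or fewer, limits chosen after the data were examined, 39 genes were on or off in each library and not alike in all 4. Of the 14 possible patterns, the one with reads at 0 and 60 µM held the most genes, 14, and its mirror, on at 30 and 90 µM, held 5. The patterns that fit the order of doses held 2 genes on at 0 µM alone, 5 on at 30, 60 and 90 µM, 1 on at 60 and 90 µM and 4 on at 90 µM alone. Apart from the gene on at 60 and 90 µM, these also set a single library apart, the control or the 90 µM library, so they do not show a dose order. The remaining genes set the 60 µM library apart, with 7 on at 60 µM alone and 1 on at 0, 30 and 90 µM. LOC116213234 had 2527, 10, 5075 and 6 counts at 0, 30, 60 and 90 µM, and LOC116196374 had 406, 0, 381 and 0. LOC116213047 had 2, 582, 1 and 633 counts, and LOC116216027 had 4, 549, 10 and 543. These 4 genes, like LOC116210933, LOC116189976, LOC116209956 and LOC116210303 above, take their large folds at 30 and 90 µM from this alternation.

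**Figure D3:**
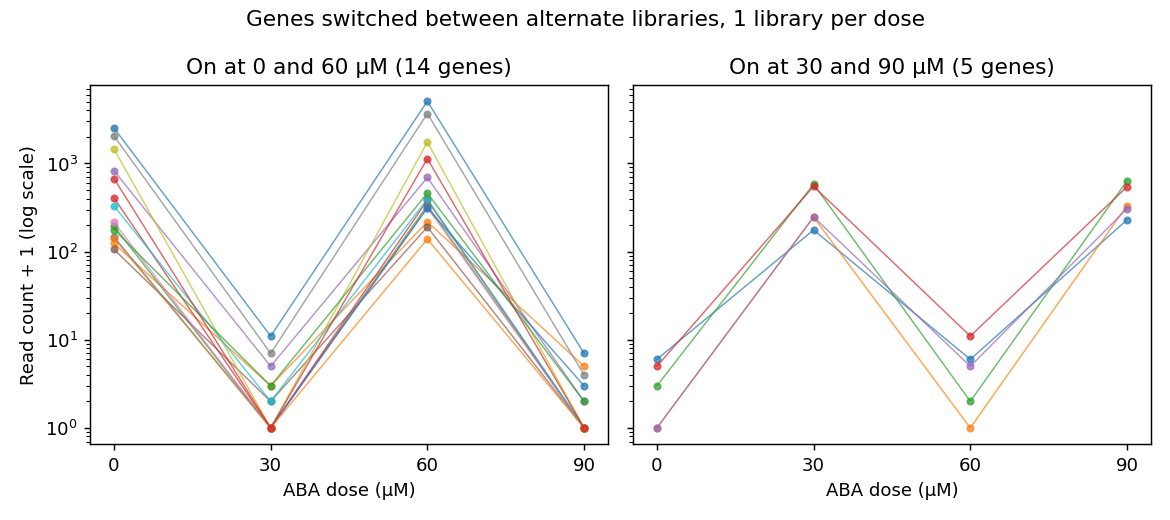
Read count plus 1 (log scale) of the 19 genes that alternate between libraries, by ABA dose (µM), with 1 line per gene and 1 library per dose. The left panel shows the 14 genes on at 0 and 60 µM and the right panel the 5 genes on at 30 and 90 µM; off libraries have at most 10 counts.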

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

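All the tests in this part were chosen after the data were seen. Against the same control library, 29 genes were more than 2-fold higher at 1 dose and more than 2-fold lower at another; with 1 library per dose the difference between doses was not tested. Such opposite calls were no more frequent than in simulated unchanged libraries, with 16 genes for 30 and 60 µM (16.8 simulated), 11 for 30 and 90 µM (15.2) and 10 for 60 and 90 µM (14.5). The simulated spread includes differences between doses, and at 30 µM it gave 1242 calls on average against 701 observed. The simulated numbers are therefore no background rate for these genes. The 45 features of the plastid genome in the table, none of them protein-coding, held 89 counts over the 4 libraries. The 347 identifiers that were not matched to the RefSeq table held 80 counts over the 4 libraries.

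In the 19 alternating on/off genes, the libraries at 0 and 60 µM resemble each other and those at 30 and 90 µM do likewise; sequencing depth is argued against, because the largest library total was 1.28 times the smallest, while on and off counts differ at least 10-fold by definition. For the 20 genes on in 2 libraries, independent spread of single libraries is argued against too, since 19 take 1 of the 3 possible splits. The exact 95% binomial interval was 75.1% to 99.9%, with genes treated as independent although some are neighbours. That split was picked as the most frequent after the values were seen, and the on/off genes on in 1 or 3 libraries were left out. A genetic difference between the plants is a candidate explanation that was not measured, and all plants were rooted cuttings of the same labelled strain. A wider set held the genes more than 2-fold apart in the same direction for 30 against 0 µM and 90 against 60 µM. In it, 22 adjacent pairs were seen against 1.05 in shuffled order. The genes that differ likewise for 60 against 0 µM and 90 against 30 µM had 11 against 2.33, and may themselves hold differences between plants. The ratio of enrichments was 4.42 (exact interval 2.06 to 10.1, with pairs treated as independent), over 198 and 257 genes placed on chromosomes, with the 10 genes that met both pairings left out. Copies that share reads or neighbours that are regulated together, and a response to ABA that is not ordered by dose, stay open and untested.

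The rRNA features were lower in the 90 µM library, with a median log2 fold of -0.98. A lower yield of RNA without a poly(A) tail in that library may account for it, but the values cannot decide. The median of the 13 snoRNA genes lay at percentile 3.0, inside the range of 95% of random lists, with 11 of them below the control and 2 more than 2-fold lower. With 1 CPM required in all 4 libraries the snoRNA median was -1.06, not set against random lists made with that filter. The median of the 3 snRNA genes lay at percentile 36.0, and their class total was not lower (0.000835% of counts against 0.000778%, with overlapping intervals). A lower level of rRNA under ABA stays open as well, untested.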

How the results depend on the processing

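The alternatives for the class medians, the on/off limits and the pairings without a shared library, and the tests they belong to, were chosen after the data were seen. Counts of genes more than 2-fold apart depended most on the rule. Taking the fold estimate alone gave 646 higher and 855 lower genes at 30 µM, 1156 and 1058 at 60 µM and 1138 and 1521 at 90 µM against the control, 1344 and 1127 for 60 against 30 µM, and 1087 and 1466 for 90 against 60 µM. A 4-fold threshold gave 82 and 126, 190 and 100, 198 and 171, 249 and 129, and 126 and 196 for the same comparisons. Requiring 1 CPM in all 4 libraries, which tests fewer genes, left 188 higher and 198 lower genes at 30 µM, 498 lower at 90 µM, and 515 lower for 90 against 60 µM. The remaining counts of this kind stayed within 1.5 times under that filter, and all of them did with no filter, DESeq2 size factors or total counts. DESeq2's Wald test called 237 rising and 70 falling genes and 53 higher and 24 lower in the ABA libraries, where edgeR called 0; the cause was not tested. The edgeR counts were 0 with DESeq2 size factors, with either other filter and without each ABA library in turn (also without the control for the line), with 1001 to 1973 genes for the line and 501 to 931 for ABA against control at an unadjusted p under 0.05; limma-voom gave 0 (1320 and 561). The median lncRNA log2 fold was -0.0799 at 30 µM with 1 CPM in all 4 libraries and -0.32 at 90 µM with total counts. The other 46 values moved by less than 0.5 of the width of the range of random lists. For the snRNA genes that took in a change of sign at 90 µM (0.58 with 1 CPM in all 4 libraries, a filter that drops LOC116189699). With the fold estimate alone, 572, 488 and 556 genes differed in the same direction in the 3 pairings without a shared library. In opposite directions there were 159, 168 and 467. Alternating on/off genes numbered 27 with limits of 50 and 3 counts and 15 with 200 and 20. For named genes, 20 values left their counting interval, 340 did not, and none past the size rule changed sign. Alternatives for the 52 gene lists were not run, because the lists had no members. No paired analysis was possible because each dose has 1 library. Depth limits genes under 0.131 CPM, the level of 3 counts in the control.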

Other observations

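Apart from the fits of the line in dose and of ABA against the control, the tests in this part were chosen after the data were seen. Genes that differed from the control in the same direction were often neighbours. Among 19089 genes placed on chromosomes, 163 adjacent pairs shared a call at 90 µM, against 55.7 on average and 80 at most in 1000 shuffles of gene order; the numbers were 54 against 10.9 at 30 µM and 108 against 38.4 at 60 µM. The longest run at 90 µM held 7 genes in a row, each more than 2-fold above the control. In it, LOC116211608 had 38, 936, 75 and 581 counts at 0, 30, 60 and 90 µM, LOC116211609 had 12, 2373, 388 and 2109, and LOC116211610 had 4, 730, 74 and 400. LOC116210073 had 73, 462, 116 and 764. Only LOC116211609 and LOC116211610 of the 7 were also more than 2-fold higher at 60 µM. All 7 had more counts at 30 and at 90 µM than at 60 µM, so this run resembles the alternation of the on/off genes and is not particular to 90 µM. A run of 6 genes was lower at 90 µM, among them LOC116207042 with 711, 343, 194 and 84 counts and LOC116207041 with 331, 174, 240 and 35. These genes were picked as members of the longest runs, after their values were seen.

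Pairs of libraries that share no library give a check that a common control cannot create. The genes that differed more than 2-fold between 0 and 60 µM and between 30 and 90 µM overlapped in the same direction 270 times (207 higher and 63 lower at the larger dose), where independent lists give 39.7, and in opposite directions 39 times, where they give 39.5. The size rule had already limited counting error before these overlaps were counted, so that excess is no further test of it. Without the 39 on/off genes, 267 same-direction genes were counted. A response between the lower and the higher doses is a hypothesis that these 270 genes may serve. It cannot be told apart from a difference between plants unrelated to dose, because 30 against 0 µM with 90 against 60 µM shared 228 genes in the same direction and 42 in opposite directions. A gene that steps with dose can meet both pairings, but 218 of the 228 were not among the 270, and 187 differed more than 2-fold the other way between 30 and 60 µM. The other pairing, 90 against 0 µM with 60 against 30 µM, gave 248 and 231. Of the 3 ways to set 2 libraries against the other 2, that of 0 and 60 µM against 30 and 90 µM held 41.0% of the variance of log2 values, that of 0 and 30 µM against 60 and 90 µM 36.8%, and the remaining one 22.1%. These shares are sums of squares, so large folds such as those of the on/off genes weigh most, and they were not recomputed without those genes. By genes at an unadjusted p under 0.05 in edgeR's test the order of the first 2 was the other way, with 961, 1661 and 781 genes.

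The control library did not stand further apart than the others. Set alone against the remaining 3 in edgeR's test, the control gave 564 genes at an unadjusted p under 0.05, the 30 µM library 581, the 60 µM library 1199 and the 90 µM library 1529, with 0 genes after adjustment each time. So 4 of the 4 choices gave as many genes as the control (real value 564, highest other 1529), and 4 choices are too few for a share under 0.05. For the line in dose, 3 of the 12 orders of the libraries gave as many genes at an unadjusted p under 0.05 (1362 for the real order, 1696 for the highest other, which swaps 0 and 30 µM). Genes that stepped the same way from each library to the next, each step beyond its 95% counting interval, numbered 289 in the real order, and 4 of the 12 orders gave as many (highest other 459). With 12 orders a share under 0.05 cannot be reached.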
